A study of Mus musculus with 8 samples.

How the data were processed

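Total RNA was measured on 8 Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample and 1 colour. Per the labels' protocols, naive CD4 T cells were stimulated through CD3 and CD28 in the presence of interleukins 1, 6 and 23, RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. The deposited values are log2 signal intensities that were background-corrected, quantile-normalised and summarised per probe set by RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. The table held 35556 probe sets with values between 3.50 and 15.03, a range that fits the log2 scale, and the values were used without a new normalization. Samples were grouped by genotype and experiment as labelled: SRC-3-deficient, SRC-3 wild type, RORγt-deficient and RORγt wild type, 2 arrays each. The titles call the 2 samples of a group biological replicates and do not say whether they came from separate mice, so p-values measure the spread between these samples.

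Probe sets were named from the platform table, which gave a symbol to 23410 of them. The 21789 with 1 symbol were used, and the 1621 with several symbols and the 12146 without a symbol were left out of the gene tests. Symbols were checked by gene ID against an annotation of assembly GRCm38, which changed 0 of them and lacked the gene IDs of 91 probe sets, and which also gave the kind of chromosome (X, Y or autosome). Coordinates are not given, because the files name no genome build for them. A probe set was kept if it reached the median of all deposited values (7.85) on at least 2 arrays, and the probe set with the highest mean over the 8 arrays stood for its symbol, which left 11128 genes. Genes below this filter that had been chosen by name were fitted without it. Some genes chosen by name are not reported here.

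Group means were fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no batch term. The 4 residual degrees of freedom were joined by 3.53 prior degrees of freedom with a prior SD of 0.08. The contrasts were SRC-3-deficient minus wild type, RORγt-deficient minus wild type, and the difference of these. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. An SE beside a log2 fold change is that of the moderated fit. The pooled spread averages over unequal experiments: relative to it the spread was 1.20 between the SRC-3 replicates and 0.756 between the RORγt replicates.

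For 28 gene lists, covering T helper fates, signalling, metabolism, coregulators, cell stress and markers of other cell types, the members past the threshold were counted over all genes and adjusted over the list alone. The 23 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists of a comparison. The lists and all settings named up to here were fixed before the data were examined. No list was chosen on these samples, a gene may be in several lists, and the list of genes known to depend on RORγt shares members with the Th17 list. The text names Ncoa3, and up to 12 genes per direction and comparison with the largest change among those past the threshold whose groups did not overlap. If fewer than 5 passed, it names the 5 with the smallest p, and predicted genes without a name are counted but not named. It also names up to 6 members of each list past the threshold by smallest p, or otherwise up to 4 by smallest p, and a set of Th17 and neighbouring cytokine genes whatever their p. Genes named beyond this rule are said to have been chosen after their values were seen.

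The fit was tested on simulated data of 11128 genes in which 66 or 67 genes per fold size and comparison were changed and the noise had the spread of each experiment. At 1.5-fold, 94.0% of changed genes were recovered in the SRC-3 comparison and 95.5% in the RORγt comparison. At 2-fold the shares were 97.0% and 100%, and at 4-fold 100% in both. These shares depend on how many genes were changed, and the simulated noise was independent between arrays. They are therefore no estimate of the share of real changes found in the SRC-3 comparison. There Il17a missed the threshold at a log2 fold change of −1.10 (limma adjusted p = 0.0567). Of the simulated calls, 17.1% were false in the SRC-3 comparison and 1.50% in the RORγt comparison. The camera test was run on the same simulated data.

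The alternatives were a new quantile normalization, a shift of each array to 1 median, no filter or a stricter one at 9.78, the mean of a gene's probe sets or each probe set on its own. The fit was also varied with the 4 arrays of a comparison alone, an intensity trend with a robust prior, array weights, the replicate number as a block, other thresholds, other set tests and leaving out each array. Fits without X- and Y-linked genes and with a sex term were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.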

Results

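Transcript levels were measured on 8 mouse gene expression arrays hybridised with RNA from CD4 T cells that had been cultured toward the Th17 fate, in which T helper cells make interleukin 17. The arrays fell into 2 experiments with 2 genotypes each, and each of the 4 groups held 2 biological replicates. In the first experiment, cells deficient in SRC-3, a coactivator that nuclear receptors recruit to their target genes, were set beside wild-type cells. In the second, cells deficient in RORγt, the nuclear receptor that directs Th17 differentiation, were set beside wild-type cells of their own experiment. The median log2 signal of all probe sets lay between 7.904 and 7.927 on the 4 arrays of the SRC-3 experiment and between 7.764 and 7.804 on the 4 arrays of the RORγt experiment. Across the 11128 genes tested, the 2 arrays of a group correlated with r between 0.989 and 0.997, and these are correlations across genes, which are not independent replicates. The median SD of a pair was 0.07 in both SRC-3 groups, and 0.04 and 0.05 in the RORγt-deficient and wild-type groups. With 2 arrays in a group, the number of arrays limits the precision of every value.

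The gene of SRC-3, Ncoa3 (probe set 10478718), was lowest on the 2 SRC-3-deficient arrays, with log2 signals of 11.15 and 10.97 beside 11.76 and 11.53 on the wild-type arrays of that experiment. Its signal was 11.78 and 11.84 on the RORγt-deficient arrays and 11.63 and 11.64 on their wild-type arrays. The mean of the SRC-3-deficient pair was 0.667 of the wild-type mean (log2 fold change −0.58, SE 0.09, n = 2 per group), and the difference missed the threshold after adjustment over all genes (adjusted p = 0.0567). The source of the deficient cells was labelled f/f, and no label says which part of the gene was removed or whether the probes of this probe set lie in it, so a remaining signal says nothing about the protein. In the RORγt comparison the log2 fold change of Ncoa3 was 0.17 (adjusted p = 0.222).

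The comparison of SRC-3-deficient with wild-type Th17 cells asks which transcripts depend on this coactivator in cells cultured with interleukins 1, 6 and 23. The cytokine gene Il17f (probe set 10353415) fell to 0.489 of its wild-type level, from a log2 signal of 11.73 ± 0.27 to 10.70 ± 0.06 (SD, n = 2; log2 fold change −1.03, SE 0.13, adjusted p = 0.0347). Maf, which encodes the transcription factor c-Maf, fell to 0.624 (log2 fold change −0.68, SE 0.08, adjusted p = 0.0198). The kinase gene Alpk2 fell to 0.467 (−1.10, SE 0.11, adjusted p = 0.0119) and the annexin gene Anxa3 to 0.535 (−0.90, SE 0.09, adjusted p = 0.0119). Akr1c18, the gene of a hydroxysteroid dehydrogenase that inactivates progesterone, rose 5.94-fold (log2 fold change 2.57, SE 0.20, adjusted p = 0.0119). Both deficient arrays lay on the same side of both wild-type arrays for each of these genes, which the rule for naming them required. This held for 37.2% of all genes in this comparison, where chance gives 33.3%. The call of Il17f was lost with the 4 arrays alone (limma adjusted p = 0.267), with array weights (0.0704) and with a sex term, which here equals leaving out deficient replicate 1. It was also lost leaving out any 1 array other than SRC-3 wild-type replicate 1. That of Maf was lost leaving out the same arrays (adjusted p between 0.0514 and 0.0746). Those of Alpk2, Anxa3 and Akr1c18 were lost without wild-type replicate 2 (adjusted p = 0.0507 each) and with the 4 arrays alone.

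In all, 25 genes passed an adjusted p of 0.05 in the SRC-3 comparison, 21 of them higher and 4 lower in the deficient cells, and 5 differed by at least 2-fold. Beside Akr1c18, the genes that rose most were Rasgef1b, a guanine nucleotide exchange factor for Ras family proteins (log2 fold change 1.42, SE 0.14), and Lratd1 (1.12, SE 0.11). They were followed by Smpdl3b, a phosphodiesterase of the sphingomyelinase family (0.97, SE 0.10) and Plagl1, a zinc finger transcription factor (0.90, SE 0.08). Ephx1, the microsomal epoxide hydrolase, Mctp1, Dlk1, a relative of the Notch ligands, Tead1, a DNA-binding partner of the Hippo pathway, Fstl4, Tigd2 and the receptor tyrosine kinase gene Erbb3 rose by 0.73 to 0.88 on the log2 scale. Several other genes named by rule missed the threshold. The log2 fold change was −1.10 for Il17a (SE 0.17, adjusted p = 0.0567), −0.68 for the interleukin 23 receptor gene Il23r (SE 0.14, adjusted p = 0.108) and −0.57 for Cd24a (adjusted p = 0.0544). It was 0.31 for Csf2, the gene of the cytokine GM-CSF (adjusted p = 0.418), 0.21 for the chemokine receptor gene Ccr6 (adjusted p = 0.534) and 0.21 for its ligand's gene Ccl20 (adjusted p = 0.741). Of the dim genes below the filter, Ifng gave −0.11 (adjusted p = 0.81), Foxp3 0.01 (adjusted p = 0.99) and Il10 −0.12 (adjusted p = 0.938), each from a fit without the filter.

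The count for SRC-3 rests on the spread shared by all 8 arrays: with the 4 SRC-3 arrays alone limma called 0 genes (827 had an unadjusted p under 0.05, and the lowest adjusted p was 0.214). With the replicate number as a block limma called 301 genes, the 25 among them, but no label says that the arrays were paired. In data simulated with the wider spread of this experiment and with changed genes added, 40 unchanged genes were called. They made up 17.1% of the simulated calls. The count and the share both depend on how many genes were changed there. In simulated data with no gene changed in the SRC-3 comparison, limma called 0 genes in it, but that noise was independent between arrays. Leaving out 1 array gave 0 genes without wild-type replicate 2 of this experiment (limma, 1457 at an unadjusted p under 0.05), 61 without wild-type replicate 1, 10 without SRC-3-deficient replicate 1, and 12 without either RORγt-deficient replicate.

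**Figure D1:**
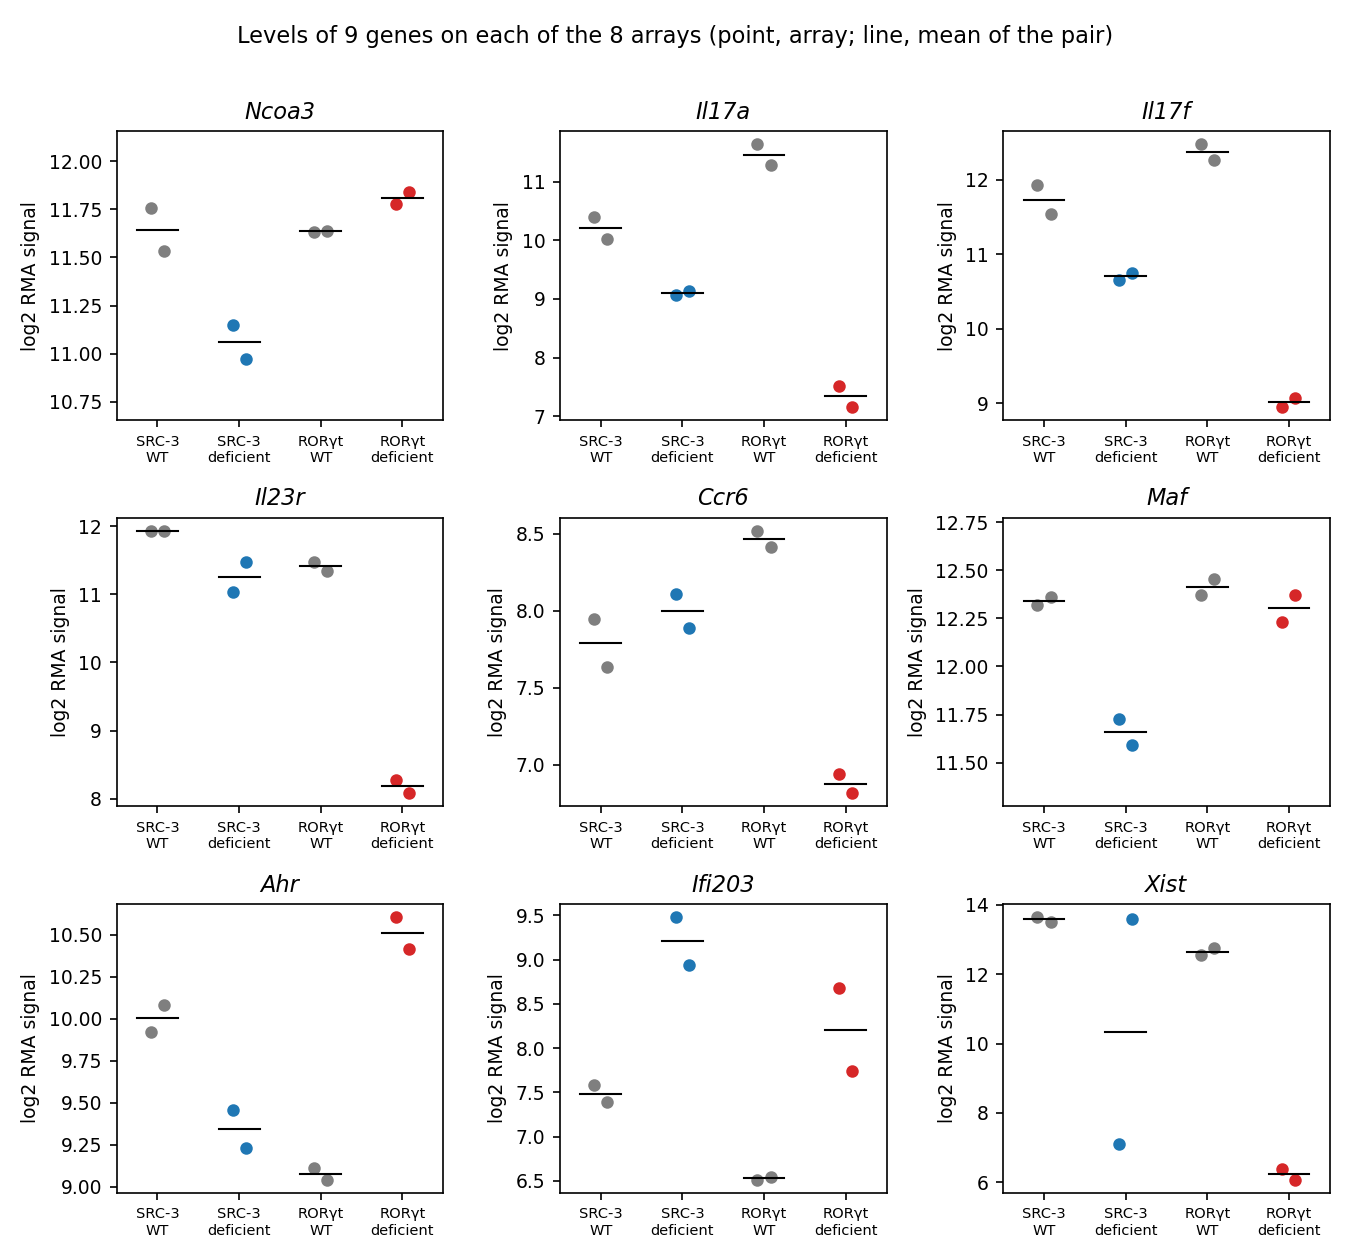
Log2 RMA signal (vertical axes) of 9 genes on each of the 8 arrays, by group (horizontal axes); points are arrays and lines are means of 2 arrays. Il17a lay at 9.10 ± 0.06 in SRC-3-deficient cells and 10.20 ± 0.26 in their wild type (SD), and at 7.34 ± 0.25 in RORγt-deficient cells and 11.45 ± 0.25 in theirs, while Xist was low on 3 arrays.

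Of the 23 measured members of the Th17 gene list, Maf and Il17f fell and the other 21 did not pass the test. Adjusted over the list alone, 7 members fell, and the list lay lower than other genes by camera (median log2 fold change −0.05, adjusted p = 0.0032, but adjusted p = 0.685 with an estimated correlation). Among its members, Ahr, the gene of the aryl hydrocarbon receptor, gave −0.66 (adjusted p = 0.0567). Of 14 genes known from the literature to depend on RORγt, 1 fell over all genes and 5 fell adjusted over the list alone (median −0.06, camera adjusted p = 0.0171, but adjusted p = 0.685 with an estimated correlation). These list calls were lost without wild-type replicate 1 of the SRC-3 experiment, where the medians were −0.02 (adjusted p = 0.339) and 0.01 (adjusted p = 0.289). The call of the RORγt-dependent genes was also lost after a new quantile normalization (median −0.10, adjusted p = 0.0888) and without the filter (median 0.09, adjusted p = 0.125). With the stricter filter the medians were −0.22 (Th17 genes) and −0.34 (RORγt-dependent genes), and without wild-type replicate 2 they were −0.13 and −0.17. They were −0.09 and −0.13 without deficient replicate 1, and −0.02 and −0.12 without deficient replicate 2. The Th17 median was −0.09 both without the filter and after quantile normalization. The 17 measured genes of the pathogenic Th17 signature held no call over all genes, and 2 rose and 3 fell adjusted over the list alone (median 0.00, camera adjusted p = 0.248). That list lay lower past the threshold without wild-type replicate 2 (median −0.16, adjusted p = 0.00179), without deficient replicate 1 (−0.07, adjusted p = 0.0406) and with the stricter filter (−0.07, adjusted p = 0.0261). Its level was higher on both replicates 1 (0.08 deficient, 0.12 wild type) than on both replicates 2 (−0.11 and −0.10), so leaving out 1 array can move it without an effect of genotype. Of the 7 measured genes of the non-pathogenic Th17 signature, Maf fell, and adjusted over the list alone 2 rose and 2 fell (median −0.11, camera adjusted p = 0.0787).

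By camera, 2 lists of other T helper fates lay higher in the SRC-3-deficient cells. The 15 measured genes of regulatory T cells had a median log2 fold change of 0.25 (camera adjusted p = 0.0032, but adjusted p = 0.685 with an estimated correlation). None of them passed over all genes by limma, and 4 rose adjusted over the list alone. The values were 1.0 for Gpr83 (adjusted p = 0.0516) and 0.84 for the semaphorin receptor gene Nrp1 (adjusted p = 0.243). The 8 measured Th2 genes had a median of 0.20 (camera adjusted p = 0.0122, but adjusted p = 0.685 with an estimated correlation), with 0 calls over all genes and 1 gene higher adjusted over the list alone. Gata3, the transcription factor gene of the Th2 fate, gave 0.80 (adjusted p = 0.121). Without wild-type replicate 2 the camera adjusted p was 0.198 for both lists, with medians of 0.14 (regulatory T cells) and 0.21 (Th2), and without wild-type replicate 1 the regulatory T cell median was 0.39. The regulatory T cell call was also lost without SRC-3-deficient replicate 1, which had the Xist level of a male (7.10; median 0.17, adjusted p = 0.189), and with the stricter filter (adjusted p = 0.0611). The Th2 call was lost without the filter (median 0.17, adjusted p = 0.0677). The 13 measured Th1 genes held no call over all genes (median 0.04, mean −0.06, camera direction down, adjusted p = 0.209), and 1 rose and 3 fell adjusted over the list alone. They lay lower past the threshold without wild-type replicate 2 (median −0.21, adjusted p = 0.000537) and with the stricter filter (−0.08, adjusted p = 0.0277).

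The 21 measured genes of the type I interferon response had the highest median of any list in the SRC-3 comparison, 0.65 (camera adjusted p = 8.77e-08, but adjusted p = 0.685 with an estimated correlation). None passed over all genes by limma, and 2 rose adjusted over the list alone. Ifi203 gave 1.72 (adjusted p = 0.0726) and Zbp1, a sensor of nucleic acids, 0.62 (adjusted p = 0.155). The list's level differed between replicates: relative to the mean of its experiment it was 0.55 and 0.10 on the SRC-3-deficient arrays and 0.00 and −0.73 on the wild-type arrays. The list's median was 0.26 without wild-type replicate 2, 1.06 without wild-type replicate 1 and 0.43 without deficient replicate 1. The 20 measured genes of cholesterol synthesis had a median of −0.16 (−0.09 without deficient replicate 2; camera adjusted p = 1.12e-05, but adjusted p = 0.685 with an estimated correlation), with 0 calls over all genes (limma) and 0 adjusted over the list alone. The 15 measured genes of the response to interleukin 1 and NF-kB had a median of 0.09 (camera adjusted p = 0.0235, but adjusted p = 0.801 with an estimated correlation), with 0 calls over all genes and 2 higher adjusted over the list alone. That call was lost without deficient replicate 1 (median 0.18, adjusted p = 0.311), without wild-type replicate 2 (median 0.02, adjusted p = 0.61) and with the stricter filter (adjusted p = 0.112). The median was 0.19 without deficient replicate 2, 0.17 without wild-type replicate 1 and 0.04 after quantile normalization. By fry, none of the lists that camera called in the SRC-3 comparison passed (lowest adjusted p 0.337).

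The comparison of RORγt-deficient with wild-type Th17 cells asks which transcripts depend on this receptor under the same culture. Il17a (probe set 10345032) fell to 0.058 of its wild-type level, from a log2 signal of 11.45 ± 0.25 to 7.34 ± 0.25 (SD, n = 2; log2 fold change −4.11, SE 0.17, adjusted p = 4.86e-05). The deficient level lay below the filter value of 7.85, where signal near background limits the values, so the size of this fall is uncertain. Il17f fell to 0.0974 (log2 fold change −3.36, SE 0.13, adjusted p = 4.86e-05) and Il23r to 0.107 (−3.23, SE 0.14, adjusted p = 4.87e-05). Ccr6 fell to 0.332 (−1.59, SE 0.12, adjusted p = 0.000606) and Csf2 to 0.475 (−1.07, SE 0.14, adjusted p = 0.00369), while Ahr rose 2.70-fold (1.43, SE 0.10, adjusted p = 0.000485). Each of these 6 genes had both deficient arrays on the same side of both wild-type arrays, as did every gene past the threshold in this comparison. Ccl20, which encodes the ligand of the receptor CCR6, rose (0.75, adjusted p = 0.0335), a call lost without RORγt-deficient replicate 1 (0.61, adjusted p = 0.195) or 2 (0.90, adjusted p = 0.0662) or wild-type replicate 2 (0.49, adjusted p = 0.177). Of the dim genes, Ifng rose (0.57, adjusted p = 0.0136), and the values were −0.03 for Foxp3 (adjusted p = 0.842) and 0.49 for Il10 (adjusted p = 0.352), in a fit without the filter.

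In all, 2157 genes passed in the RORγt comparison, 1114 higher and 1043 lower in the deficient cells, and 122 of them changed by at least 2-fold, 72 higher and 50 lower. The groups did not overlap for 70.0% of all genes, where chance gives 33.3%. The genes that fell most, after Xist and the Th17 genes above, were Olfr60 (log2 fold change −3.13), Timd2 (−2.38), Ermn (−2.28), Cd93 (−2.27), and the endocytic adaptor gene Dab2 (−2.08). The homeobox gene Vax2 (−2.04), the leukotriene receptor gene Cysltr2 (−1.94) and Slc15a3 (−1.88) came next. The genes that rose most were the Y-linked Eif2s3y (5.74), Prg4, the gene of the secreted lubricant proteoglycan 4 (3.08, SE 0.13), the interferon-induced GTPase gene Iigp1 (2.40), Tns4 (2.23), Ifi209 (2.08), Plac8 (2.08), and Klrd1, which encodes the NK receptor chain CD94 (1.90, SE 0.13). They were followed by the δ chain V segment Trdv2-2 (1.86), Nt5e, which encodes the ectonucleotidase CD73 (1.81), Ifi203 (1.68), Slamf6 (1.61) and Sntb1 (1.5). Their adjusted p lay between 4.86e-05 (Prg4) and 0.0456 (Eif2s3y).

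The sex of the mice moved with this genotype. Xist, which is transcribed from the inactive X chromosome of females, gave log2 signals of 6.37 and 6.08 on the RORγt-deficient arrays and 12.55 and 12.76 on their wild-type arrays (log2 fold change −6.43, SE 1.68, adjusted p = 0.0351). The Y-linked Eif2s3y gave 10.47 and 10.48 on the deficient arrays and 4.84 and 4.63 on the wild-type arrays (5.74, SE 1.63, adjusted p = 0.0456). In the SRC-3 experiment, deficient replicate 1 alone showed this male pattern, with an Xist signal of 7.10 beside 13.60, 13.65 and 13.52 on the other arrays. The SRC-3-deficient pair was thus of mixed sex, which widened the shared spread of Xist and Eif2s3y and so the SE given above. With the 4 arrays of the RORγt comparison alone, the limma adjusted p was 7.22e-06 for Xist and 3.11e-06 for Eif2s3y. Of 317 X-linked genes tested, 62 passed in the RORγt comparison (19.6%), as did 2090 of 10781 autosomal genes (19.4%).

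Leaving out 1 RORγt-deficient array left 486 (without replicate 1) or 1001 (without replicate 2) genes past the threshold. Leaving out 1 of their wild-type arrays left 626 (without replicate 1) or 558 (without replicate 2). With a term for sex, which only the SRC-3-deficient pair can estimate, 95 genes passed and the median SE rose from 0.08 to 0.13 on the log2 scale. In that fit Il17a (−4.03, adjusted p = 0.00889), Il17f (−3.27, adjusted p = 0.00733) and Il23r (−2.79, adjusted p = 0.0031) passed and Csf2 did not (−0.93, adjusted p = 0.108). The sex term cannot be told apart from the replicate number in the SRC-3-deficient pair. Several lists shifted the same way between the 2 female SRC-3 wild-type arrays. The interferon, T cell activation, cell cycle, cholesterol synthesis and pathogenic Th17 lists were among them. Their values with the sex term therefore do not isolate sex.

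Of the 14 measured genes known to depend on RORγt, 9 fell and 4 rose, with the same counts adjusted over the list alone (median −1.21, camera adjusted p = 6.41e-05, but adjusted p = 0.419 with an estimated correlation). Beside the genes above, Furin, the gene of a proprotein convertase, fell (−1.40). Of the 23 measured Th17 genes, 10 fell and 5 rose, and 12 fell and 5 rose adjusted over the list alone (median −0.23, −0.15 without the filter, camera adjusted p = 0.00178, but adjusted p = 0.466 with an estimated correlation). The pathogenic Th17 signature went both ways, with 5 of 17 measured genes lower, Csf2 and the transcription factor gene Bhlhe40 (−0.65) among them, and 4 higher, Stat4 (0.45) and Il18r1 (0.61) among them. The counts were the same adjusted over the list alone (median −0.08, camera adjusted p = 0.57). With the sex term, which also takes up the replicate number, the median was −0.32 (camera adjusted p = 0.047). The level of this signature overlapped between the groups, with −0.06 and 0.09 on the deficient arrays and 0.05 and −0.07 on the wild-type arrays. Of the 7 measured genes of the non-pathogenic signature, 3 rose: Ahr, Il6st, the gene of the signalling chain gp130 (1.08), and the Ikaros family gene Ikzf3 (0.61). Adjusted over the list alone, 3 rose and 1 fell (median −0.01, mean 0.39, camera direction up, adjusted p = 0.189, but fry adjusted p = 0.000901).

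Of the 16 measured naive and memory T cell genes, 9 rose and 1 fell, and 10 rose and 2 fell adjusted over the list alone (median 0.46, camera adjusted p = 0.00324, but adjusted p = 0.419 with an estimated correlation). That list call was lost with the sex term (median 0.36, adjusted p = 0.0748). Klf2, a transcription factor gene needed for T cell exit from lymphoid organs, rose (1.43), as did S1pr1, the sphingosine 1-phosphate receptor gene that Klf2 controls (1.05). Dapl1 (1.26), Klf3 (0.96) and Igfbp4 (0.74) rose too, while the interleukin 7 receptor gene Il7r fell (−0.44). Of the 13 measured Th1 genes, 5 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (median 0.34, camera adjusted p = 0.189, but adjusted p = 0.00891 without the filter). Of the 8 measured Th2 genes, 4 rose, among them Penk (1.12), Gata3 (0.86) and Il13 (0.34), and Il24 fell (−1.32). The counts were the same adjusted over the list alone (median 0.25, camera adjusted p = 0.0566). The Th2 list passed without RORγt-deficient replicate 1 (median 0.42, adjusted p = 0.00602) and without wild-type replicate 2 (0.26, adjusted p = 0.039). It also passed after quantile normalization (adjusted p = 0.0354) and with each probe set on its own (adjusted p = 0.0493). Of the 15 measured genes of regulatory T cells, 4 rose, namely Nt5e, Nrp1 (0.91), Entpd1, the gene of the ectonucleotidase CD39 (0.71), and Gpr83 (0.52). The counts were the same adjusted over the list alone (median 0.13, camera adjusted p = 0.149). The male pattern described above was on both deficient arrays behind each of these lists.

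Of the 20 measured cholesterol synthesis genes, 10 fell and 0 rose, and 12 fell adjusted over the list alone (median −0.27, camera adjusted p = 6.41e-05, but adjusted p = 0.419 with an estimated correlation). The genes with the smallest p were Idi1 (−0.64), Cyp51 (−0.74), Msmo1 (−0.82), Insig1 (−0.68), Sqle, the squalene epoxidase gene (−0.70), and Mvd (−0.41). Of the 21 measured type I interferon response genes, 8 rose and 0 fell, and 12 rose adjusted over the list alone (median 0.87, camera adjusted p = 6.41e-05, but adjusted p = 0.664 with an estimated correlation). Ifit2 (0.71), Zbp1 (0.83), Mx1 (1.43) and Oasl2 (1.32) were among them. The list's level relative to the mean of its experiment was 0.78 and 0.14 on the deficient arrays and −0.43 and −0.42 on the wild-type arrays. With the sex term this list's median was 0.45 (camera adjusted p = 0.225), and without RORγt-deficient replicate 1 its median was 0.58. That term also takes up the replicate number, by which this list shifted between the 2 female SRC-3 wild-type arrays too (0.00 and −0.73). Of the 15 measured genes of the response to interleukin 1 and NF-kB, 6 fell and 0 rose, and 9 fell and 1 rose adjusted over the list alone (median −0.24, camera adjusted p = 0.00604, but adjusted p = 0.582 with an estimated correlation). The decoy receptor gene Il1r2 (−1.35), the adhesion molecule gene Icam1 (−0.42) and Nfkbia, whose protein inhibits NF-kB (−0.37), fell. Of the 22 measured T cell activation genes, Csf2 and Tnfaip3 (−0.59) fell, also adjusted over the list alone, and none rose (median −0.28, camera adjusted p = 0.00329, but adjusted p = 0.719 with an estimated correlation). The activation list's median was −0.14 without RORγt-deficient replicate 1, −0.47 without replicate 2 and −0.52 with the sex term, and its level was −0.30 and −0.04 on the deficient arrays and 0.13 and 0.18 on the wild-type arrays. The cholesterol median was −0.56 with the sex term. By fry, 3 of these lists missed the threshold, with an adjusted p of 0.159 for interferon, 0.0604 for NF-kB and 0.243 for activation genes.

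**Figure D2:**
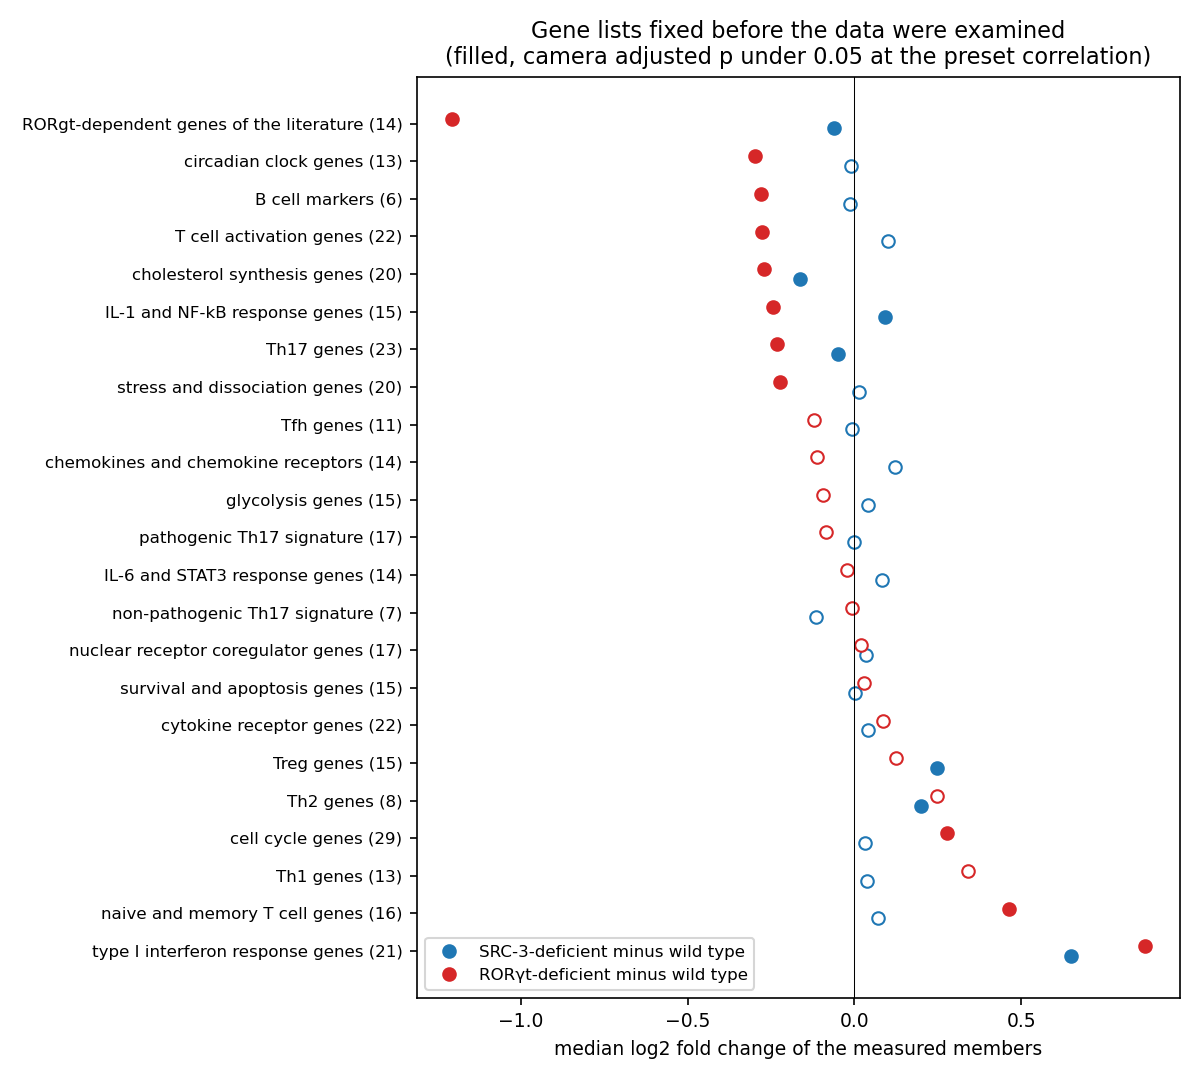
Median log2 fold change (horizontal axis) of the measured members of 23 gene lists (vertical axis, number of members in brackets) in both comparisons; filled points had a camera adjusted p under 0.05 at the preset correlation of 0.01, and none kept it with an estimated correlation. The RORγt-dependent genes lay at −1.21 in the RORγt comparison and −0.06 in the SRC-3 comparison, and the interferon list at 0.87 and 0.65.

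Whether the genes that depended on RORγt moved with SRC-3 deficiency was asked across the 2 experiments, which share no array. The 1043 genes lower in RORγt-deficient cells had a median log2 fold change of −0.08 in the SRC-3 comparison (quartiles −0.17 and 0.00), and 76.4% of them lay below 0 (camera p = 2.5e-20, p = 0.0484 with an estimated correlation, but fry p = 0.0552). With the lower genes called anew in each fit, the median was −0.03 without SRC-3 wild-type replicate 1 (1206 genes) and −0.12 without RORγt wild-type replicate 2 (259 genes). The 1114 genes higher in RORγt-deficient cells had a median of 0.12 (quartiles 0.04 and 0.22), and 84.1% of them lay above 0 (camera p = 8.09e-19, p = 0.00233 with an estimated correlation, fry p = 0.000417). Of the 21 genes that rose with SRC-3 deficiency, 18 also rose with RORγt deficiency, where independent sets would share 2.10. Lratd1 (1.21), Smpdl3b (0.98), Mctp1 (1.04), Erbb3 (1.16) and Akr1c18 (0.93, adjusted p = 0.0185) were among them, with these log2 fold changes in the RORγt comparison. Of the 4 genes that fell, 3 also fell with RORγt deficiency, namely Il17f, Alpk2 (−1.0) and Anxa3 (−0.76), where independent sets would share 0.375. The fourth, Maf, gave −0.11 in the RORγt comparison (adjusted p = 0.354). No gene passed in opposite directions, where independent sets would give 1.97 and 0.40. Both comparisons share the spread of each gene from the same fit. Their calls are therefore not independent sets, and the numbers given for independent sets can be too low.

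Across the 11128 genes, the log2 fold changes of the 2 comparisons correlated with Pearson's r of 0.513 and Spearman's rho of 0.413 (covariance 0.0266), and genes are not independent replicates. The male pattern was on both RORγt-deficient arrays and on SRC-3-deficient replicate 1, which moves Xist and Eif2s3y the same way in both comparisons. Pearson's r was 0.458 without X- and Y-linked genes and 0.409 without SRC-3-deficient replicate 1. Of the 2157 genes that passed in the RORγt comparison, 80.4% had the same sign in the SRC-3 comparison, as did 63.8% of all genes.

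**Figure D3:**
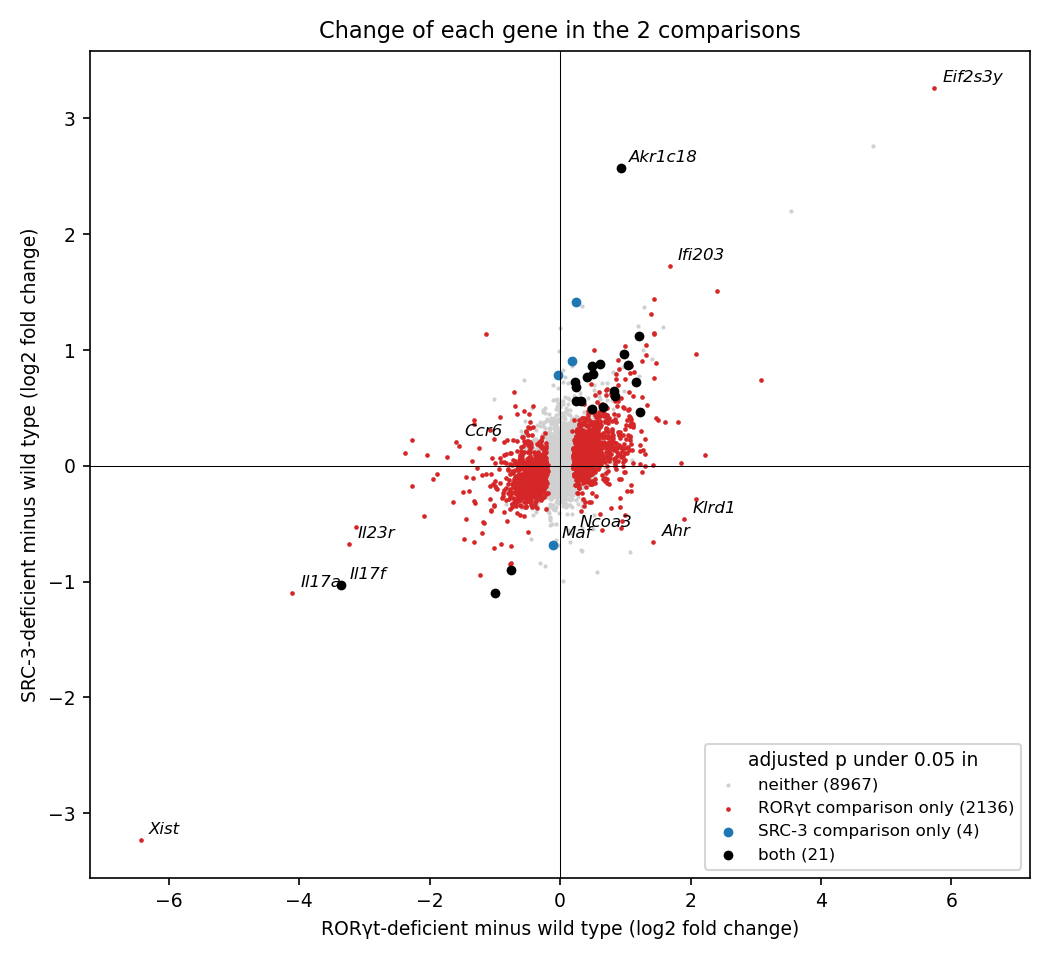
Log2 fold change of each of 11128 genes in the RORγt comparison (horizontal axis) and the SRC-3 comparison (vertical axis), coloured by where the adjusted p was under 0.05. The 21 genes past the threshold in both had the same sign in both, and Il17a and Il17f lay at −4.11 and −3.36 on the horizontal axis and −1.10 and −1.03 on the vertical axis.

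The effects of SRC-3 and of RORγt deficiency were set against each other by testing their difference. Each effect comes from its own experiment, so a difference due to genotype cannot be told apart from one due to experiment. The wild-type arrays of the 2 experiments differed for 58.5% of genes by limma, and sex moved with genotype in the RORγt comparison. Il17a fell less with SRC-3 deficiency than with RORγt deficiency (difference of log2 fold changes 3.01, SE 0.24, adjusted p = 0.00343), as did Il17f (2.33, SE 0.18, adjusted p = 0.00325). Il23r (2.55, SE 0.20, adjusted p = 0.00325), Ccr6 (1.80, adjusted p = 0.00596) and Csf2 (1.38, adjusted p = 0.0228) differed in the same direction. Ahr differed the other way, with −0.66 in the SRC-3 comparison and a rise of 1.43 in the RORγt comparison (difference −2.09, SE 0.15, adjusted p = 0.00293). The difference for Ncoa3 itself was −0.76 (adjusted p = 0.0394), and that for Maf missed the threshold (adjusted p = 0.0523). In all, 186 genes differed, 103 with the more positive effect in SRC-3 deficiency and 83 with the more negative. Of these, 173 had passed in the RORγt comparison alone, 3 in the SRC-3 comparison alone (Rasgef1b, Plagl1 and Fstl4), 4 in both and 6 in neither. The signs of the 2 effects were opposite for 109, the same with the larger effect in RORγt deficiency for 73, and the same with the larger effect in SRC-3 deficiency for 4, Akr1c18 among them (difference 1.64, adjusted p = 0.0399). Most of the 186 genes had no SRC-3 call, so many of these signs rest on SRC-3 values that did not pass. Vax2, for example, gave 0.09 there (limma adjusted p = 0.870), and no gene passed in opposite directions in the 2 comparisons.

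The count of differing genes was 60 without SRC-3-deficient replicate 2, 121 without wild-type replicate 2 of that experiment, 23 and 38 without RORγt-deficient replicates 1 and 2, and 15 without either of their wild-type replicates.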

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

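The tests of the lists' difference, the tests of Xist with the Y-linked genes and of Klrd1, and the fit with a sex term were chosen after the data had been seen.

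The effects of SRC-3 and RORγt deficiency differed, by the test of the difference itself, for 186 genes, where genotype and experiment cannot be told apart. The differences that follow are SRC-3 effects minus RORγt effects on the log2 scale. Among Th17 cytokines and receptors, the difference was 3.01 for Il17a, 2.33 for Il17f, 2.55 for Il23r, 1.80 for Ccr6 and 1.38 for Csf2, and for the convertase gene Furin it was 1.19. Among transcription factor genes it was −2.09 for Ahr, −1.42 for Klf2, −0.76 for Hlx, −0.96 for Pou2af1, 1.21 for Atf3, 0.65 for Bhlhe40, 0.99 for Nr1d1 and 0.72 for Plagl1. Among other genes with the more positive effect in SRC-3 deficiency it was 1.64 for Akr1c18, 1.17 for Rasgef1b, 0.81 for Fstl4, 2.10 for Cd93, 1.83 for Cysltr2, 1.65 for Dab2 and 2.50 for Ermn. It was 2.60 for Olfr60, 1.81 for Slc15a3, 2.49 for Timd2, 2.13 for Vax2 and 1.34 for Cd74. It was 1.39 for Il1r2, 0.76 for Icam1, 0.74 for Gadd45b, 0.66 for Chac1 and 0.71 for Bcl2l1. Igfbp7, chosen after its values were seen, differed by 2.27, with 1.14 in the SRC-3 comparison (adjusted p = 0.0905) and −1.13 in the RORγt comparison (adjusted p = 0.0126). With the more negative effect in SRC-3 deficiency it was −2.37 for Klrd1, −2.36 for Plac8, −2.34 for Prg4, −2.13 for Tns4, −1.83 for Trdv2-2, and −1.24 for Slamf6. It was −1.11 for Sntb1, −0.86 for Il6st, −0.81 for Il17ra, −0.78 for S1pr1, −0.76 for Ncoa3, −0.71 for Bcl2l11 and −0.68 for Igfbp4.

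The camera test of the difference passed its threshold for 12 of 23 lists, and none of them passed with an estimated correlation, where the lowest adjusted p was 0.159. The median difference was 0.18 for Th17 genes, 0.76 for genes known to depend on RORγt, 0.44 for T cell activation, and 0.28 for the response to interleukin 1 and NF-kB. It was 0.20 for cholesterol synthesis, 0.28 for the circadian clock, 0.20 for stress and dissociation and 0.27 for B cell markers. It was −0.57 for the non-pathogenic Th17 signature, −0.31 for Th1 genes, −0.29 for naive and memory T cell genes and −0.35 for the cell cycle.

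Probe sets outside the gene tests also changed. Of 5919 probe sets without a symbol, 1 passed in the SRC-3 comparison and 114 in the RORγt comparison (56 higher, 58 lower). Of 902 probe sets with several symbols, 51 passed in the RORγt comparison (22 higher, 29 lower) and 0 in the SRC-3 comparison by limma.

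The RORγt-deficient mice and their wild-type mice differed in sex by Xist and the Y-linked genes, so sex was weighed against genotype for the calls of that comparison. Across Xist and the Y-linked Eif2s3y, and Kdm5d and Uty, which were chosen after their values were seen, the difference between the male and the female SRC-3-deficient array regressed on the RORγt log2 fold change with a slope of 1.09. The sexes were read from such genes, so this slope was given beforehand and tests nothing. Across the 2094 called genes not assigned to X or Y the same slope was 0.0164, below the 0.5 set beforehand by more than the size of −0.0654 found between 2 female wild-type arrays, which argues against sex as the source of most of these changes, though the slope rests on 1 male and 1 female array. Of these genes, 89.6% kept their call after a new quantile normalization and 93.7% after a shift to 1 median. The deposited values were already quantile-normalised and the medians of these 4 arrays lay between 7.764 and 7.804. Both settings could therefore change little here and cannot decide on normalization between arrays. The genotype itself may account for these calls. Single genes stay open, because the sex term left 95 calls with a median SE of 0.13 in place of 0.08.

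Most RORγt-dependent genes moved the same way, at smaller size, in the SRC-3 comparison. The slope of the SRC-3 on the RORγt log2 fold changes was 0.247 over the 2094 genes called there and not assigned to X or Y. Of all genes called in the RORγt comparison, 80.4% had the same sign. Ccr6, Csf2, Ahr and Klrd1, among the genes that changed strongly with RORγt deficiency, had the opposite sign, though none of their SRC-3 values passed. The sex of SRC-3-deficient replicate 1 is argued against by a slope of 0.238 without that array. The other splits of the 4 SRC-3 arrays had slopes of 0.0409 and −0.0245, so no drift of cultures showed in them. A culture difference that fell along the genotype would not appear in those splits, and 4 arrays allow few splits, so such a difference is not excluded. The slope of the genotype split was 0.239 over the 2086 of the called genes outside the interferon list. Lower RORγt activity in SRC-3-deficient cells is a candidate explanation that stays open: the median of the 14 genes known to depend on RORγt was −0.0625 (camera adjusted p = 0.0171, but adjusted p = 0.685 with an estimated correlation), and no array measures the receptor's activity.

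Klrd1, which NK cells and CD8 T cells express, rose by 1.90 in the RORγt-deficient cultures. Cells of these types could bring their other transcripts too. The 11 other measured markers had a median log2 fold change of 0.0988 (SE 0.0521), but most lay below the filter, where a change may be hidden, so this explanation stays open. Gzmb (0.91) and Ifng (0.57), which such cells and activated T cells share, rose. Prf1 (0.30, level 8.24 in the deficient cells) and Cd8b1 (0.18, level 9.14) were the brightest of them. A change inside the T cells was not tested.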

How the results depend on the processing

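The fits with a sex term and without X- and Y-linked genes were chosen after the data had been seen. Counts stayed within 1.5 times the count given for the SRC-3 comparison, the RORγt comparison and their difference after a new quantile normalization (22, 1955 and 132 genes), a shift to 1 median (23, 2198 and 171), no filter (31, 1835 and 154), and without X- and Y-linked genes (24, 2112 and 184), and with the mean of a gene's probe sets or each probe set on its own. The share of genes higher among those past the threshold went from 84% to 72.7% (SRC-3) and from 55.4% to 46.2% (difference) after quantile normalization, and to 43.9% (difference) and from 51.6% to 58.6% (RORγt) after the shift.

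In the SRC-3 comparison, the 25 genes became 14 with the stricter filter, 0 with 4 arrays (limma, 827 at an unadjusted p under 0.05), 47 with a trend and robust prior, 10 with array weights, 129 at an adjusted p under 0.1, 5 at 2-fold, 10 with the sex term, and 0 to 61 leaving out 1 array. In the RORγt comparison, the 2157 became 3389 with 4 arrays, 3679 with array weights, 122 at 2-fold, 133 at 2-fold apart without a test, 95 with the sex term (90 of them shared) and 486 to 2539 leaving out 1 array. The 186 of the difference became 119 with the stricter filter, 470 at an adjusted p under 0.1, 57 at 2-fold, 60 with the sex term and 15 to 264 leaving out 1 array; 4 arrays give no value for it. With the replicate number as a replicate block the counts were 301 (25 shared), 3411 and 945, and Il17a, Ncoa3 (adjusted p = 0.00671 each) and Il23r (0.0268) passed in the SRC-3 comparison, as did the T cell activation list by camera (0.0457, and 0.19 without the block). Il17a (0.048) and Ncoa3 (0.0464) also passed there with the trend and robust prior. Deviations with the same number correlated with 0.536 in the SRC-3 and 0.00174 in the RORγt experiment, which does not establish pairs from 2 pairs each.

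The correlation across genes was 0.447 without the filter and 0.357 (without SRC-3 wild-type replicate 1) to 0.547 leaving out 1 array. The SRC-3 median of the genes lower in RORγt deficiency (−0.0813) missed the threshold by fry. Of the lists past camera's threshold, 0 of 7 (SRC-3) and 0 of 11 (RORγt) passed with an estimated correlation, and 0 of 7 (SRC-3) and 7 of 11 (RORγt) by fry, which called 9 lists in the RORγt comparison. With the sex term both comparisons rest on SRC-3-deficient replicate 2, which pushes them to agree, so that fit says nothing on their agreement. For the SRC-3 comparison that fit equals the one without deficient replicate 1, and for the difference the one without deficient replicate 2. The T cell activation list ranged from a median of −0.119, reversed, without SRC-3 wild-type replicate 2 to 0.324 without replicate 1. With the sex term Eif2s3y (−0.55) and Xist (0.0682) reversed in the RORγt comparison, since that term takes up the male pattern. Of 173 named genes, 16 lost their SRC-3 call with 4 arrays or without wild-type replicate 2, and 91 their RORγt call with the sex term, whose error is wider. Without RORγt-deficient replicate 1 or 2, 61 and 37 lost their RORγt call, and without wild-type replicate 1 or 2, 60 and 62. List calls lost in the SRC-3 and RORγt comparisons numbered 2 and 1 without the filter, 2 and 1 with the stricter filter (where the called Th2 and B cell lists, 1 in each, were too small to test), and 2 and 3 with the sex term. For the other shifts the cause was not tested. Signal near background limits the probe sets below the filter.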

Other observations

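The comparison of the wild types with each other was chosen after the data had been seen.

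Members of several further lists passed the threshold in the RORγt comparison. Of the 13 measured genes of the circadian clock, 4 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (median −0.30, camera adjusted p = 0.004, but adjusted p = 0.419 with an estimated correlation and 0.0774 with the stricter filter). That median was −0.18 without RORγt-deficient replicate 1, −0.20 without the filter and −0.45 with the sex term. Nr1d1, the gene of the repressor REV-ERBα and a target of ROR proteins in the clock, fell (−1.06, adjusted p = 0.000485), as did Bhlhe40 (−0.65), Arntl, which encodes BMAL1 (−0.48), and the repressor gene Cry1 (−0.58), while Dbp rose (0.51). Of the 20 measured stress and dissociation genes, 7 fell and 0 rose, and 10 fell adjusted over the list alone (median −0.22, camera adjusted p = 7.38e-05, but adjusted p = 0.205 with an estimated correlation). Gadd45b (−0.73), Atf3 (−0.69), Chac1 (−0.63), the heme oxygenase gene Hmox1 (−0.63) and the chaperone gene Hspa1a (−0.51) were among them. Of the 29 measured cell cycle genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (median 0.28, camera adjusted p = 0.00578, but adjusted p = 0.734 with an estimated correlation, 0.0544 without RORγt wild-type replicate 2 and 0.285 by fry). With the sex term, which also takes up the replicate number, that median was 0.76. Kif11 (0.71), Top2a (0.56), Bub1b (0.77) and Ccnb2 (0.81), all genes of mitosis, rose, and E2f1 fell (−0.22). The male pattern was on both deficient arrays here too.

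Of the 15 measured survival and apoptosis genes, Bcl2l1, whose main product Bcl-xL protects cells (−0.62), Tnfrsf10b (−0.70) and Bid (−0.26) fell. The pro-apoptotic Bcl2l11 (0.36) and the protective Mcl1 (0.35) rose, with the same counts adjusted over the list alone (median 0.03, mean −0.04, camera direction down, adjusted p = 0.905). Of the 11 measured genes of follicular helper T cells, 3 rose, Slamf6, Pou2af1 (1.10) and Tox (0.80), and 3 fell, Il21 (−0.59), Cd200 (−0.45) and Bcl6 (−0.37), with 4 in each direction adjusted over the list alone (median −0.12, mean 0.16, camera direction up, adjusted p = 0.826, but fry adjusted p = 0.00848). Of the 22 measured cytokine receptor genes, 8 rose, Il17ra (0.96) and Ifngr1 (0.79) among them, and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.56). The 14 measured genes of the response to interleukin 6 and STAT3 held 2 that rose, Il6st and Socs3 (0.67), and 2 that fell, Il21 and Bcl6 (camera adjusted p = 0.975). The 14 measured chemokine and receptor genes also held 2 that rose and 2 that fell (camera adjusted p = 0.473). Both lists had the same counts adjusted over the list alone. Of the 17 measured coregulator genes, the acetyltransferase gene Kat2b rose (0.50), also adjusted over the list alone (camera adjusted p = 0.407 for the list). Of the 15 measured glycolysis genes 0 passed by limma over all genes or adjusted over the list alone (camera adjusted p = 0.407, but median −0.18 and adjusted p = 0.00112 with the sex term).

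In the SRC-3 comparison, 0 members of these 10 lists passed over all genes by limma. Adjusted over the list alone, 5 rose and 4 fell among cytokine receptors, 2 rose and 2 fell among survival genes, 2 rose among follicular helper genes, 1 rose among stress genes, and 1 fell in each of the cell cycle, chemokine and coregulator lists. The camera adjusted p lay between 0.0787 (cell cycle, median 0.03, mean −0.03, camera direction down) and 0.981. The cell cycle list's level followed the replicate number and not the genotype, with −0.18 and 0.19 on the deficient arrays and −0.17 and 0.21 on the wild-type arrays. Leaving out 1 array unbalanced these numbers, and the list then lay lower past the threshold without deficient replicate 2 (median −0.20, adjusted p = 1.44e-05) and without wild-type replicate 1 (−0.22, adjusted p = 8.02e-06). It also passed with the stricter filter (adjusted p = 0.0277) and with each probe set on its own (adjusted p = 0.0472). The response to interleukin 6 and STAT3 lay higher without wild-type replicate 1 (median 0.17, adjusted p = 0.000905) and glycolysis without deficient replicate 2 (0.05, adjusted p = 0.0191). The naive and memory T cell list held 2 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.576), and the T cell activation list 0 (median 0.10, camera adjusted p = 0.19). With the replicate number as a block, the activation list passed as higher by camera. The activation list's level was 0.21 and −0.09 on the deficient arrays and 0.195 and −0.26 on the wild-type arrays, again by replicate number. So it lay higher past the threshold without deficient replicate 2 (median 0.24, adjusted p = 0.00139) and without wild-type replicate 1 (0.32, adjusted p = 4.09e-08), and lower without wild-type replicate 2 (−0.12, adjusted p = 0.0218).

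Markers of other cells were mostly dim. Of the 6 measured B cell markers, Cd74, the invariant chain gene (−0.71), Ebf1 (−1.33) and Fcmr (−0.35) fell with RORγt deficiency, also adjusted over the list alone (median −0.28, camera adjusted p = 0.0292, but adjusted p = 0.419 with an estimated correlation). That call was lost without RORγt-deficient replicate 1 (median −0.23, adjusted p = 0.068) and without wild-type replicate 1 (−0.24, adjusted p = 0.0866). It was also lost without the filter (−0.04, adjusted p = 0.301) and with the sex term (−0.41, adjusted p = 0.058). In the SRC-3 comparison 0 of these markers passed by limma, 1 rose adjusted over the list alone, and the camera adjusted p was 0.981. Of 3 measured myeloid markers, Ctss rose (0.30) and Cst3 fell (−0.27) with RORγt deficiency, of 3 markers of γδ T cells and innate lymphoid cells Id2 fell (−0.37), and of 4 thymocyte markers 0 passed by limma. Among 3 measured CD8 T cell and NK cell markers Klrd1 rose, and 0 erythroid markers reached the filter. In the SRC-3 comparison none of these members passed over all genes by limma.

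The wild-type arrays of the 2 experiments differed for 6508 of 11128 genes (58.5%), 3038 higher and 3470 lower in the wild type of the SRC-3 experiment. The median signal also differed between the experiments. A difference between the cells cannot be told apart here from one in culture, array processing or normalization. The first principal component held 68.9% of the variance and separated the experiments. Of the 138 genes called in the RORγt comparison that had several kept probe sets, 7 had probe sets of opposite sign.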
